A study of Drosophila melanogaster with 6 samples.

How the data were processed

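Total RNA of 30 fly heads per sample, taken after 3 to 4 days of light-dark entrainment per the labels' protocols, was hybridised to Affymetrix Drosophila 2.0 arrays, 1 array per sample. The 6 arrays were used, 2 per genotype and 3 per time. The deposited values are log2 probe set signals, a scale read from the values themselves, which have near-equal medians on all arrays and lie on a narrow positive range. They were made with Affymetrix Expression Console per the submitters' processing notes, and neither its version nor the summarisation and normalization method is given in the sources used here. No further normalization was applied. The deposited table held 10956 probe sets, each of which reached 4.00 or more on at least 1 array, so that dim probe sets appear to have been left out before, and no values below that level on all 6 arrays were seen. For arrays the number of arrays, here 6, limits the precision.

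Probe sets were named from the platform annotation, with symbols updated by gene ID through the RefSeq table of assembly Release 6 plus ISO1 MT. Of the probe sets 9286 had 1 gene, 276 several and 1394 none listed, and 63 were control probe sets. Of those with 1 gene 9260 were matched by gene ID. No gene was named from a probe set with several. The probe set with the highest mean stood for its gene, which gave 8516 genes. Genes with a mean above the 40th percentile of all probe sets, 6.79, were tested, 5489 in number. Because dim probe sets were missing already, this filter lies higher than intended, and many members of the lists below, all digestive tract markers among them, were not tested. Among 616 probe sets with no listed gene above the filter, tested apart, 56 changed in the over-expression-labelled genotype, 90 in the RNAi-labelled genotype, 198 between the 2 and 4 with time.

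Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit with genotype and time as additive terms on all 6 arrays and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Each gene had 2 residual degrees of freedom and the prior added 3.80. With 1 array per genotype and time, the interaction of genotype and time is part of the residual and was not tested. Each log2 difference between genotypes is the mean over both times, and that between times is the mean over the 3 genotypes. SE is the moderated standard error. Genes 1.5-fold or more apart in 1 direction at both times were counted without a model. The median SE was 0.104 for genotype and 0.0851 for time. Tested on simulated data of 5489 genes with 200 changed, 20 times, the fit found 66.0% of changes of 0.5 log2 units, 99.1% of 1 and 99.8% of 2 between the over-expression-labelled and control genotypes, with 6.93% false among its calls, and for time 88.8%, 99.5% and 100% with 6.25% false. These simulated arrays vary independently between genes, which real arrays need not do.

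Before the data were examined, 25 gene lists were fixed, 16 for pathways (the core clock and its output, sugar, lipid and amino acid metabolism, sugar-responsive transcription, phototransduction, immunity, stress, detoxification, neuropeptides, ribosomal and respiratory chain proteins and hormone response) and 9 for cell types and sexes. Lists were tested against the other genes with camera at a correlation of 0.01, adjusted over the 23 lists with at least 4 genes tested. They were tested again with an estimated correlation, where camera takes only the 2 residual degrees of freedom. Few lists could pass there, whatever their correlation. fry tested each list against no change, which is another question. Some genes are in 2 lists, such as *Lsd-1* and *trpl*. The comparisons, the processing alternatives and the rule for named genes were fixed then too. The rule named *cbt*, the core clock, up to 10 genes per direction with the largest differences that passed in 1 direction in every pair of arrays, and up to 4 genes per list with the largest differences. Genes with only a CG number were left unnamed, and list members that did not pass are named only for the immune list and *Pepck1*, plus *Galphaq*, a choice made after the values were seen, as were the genes named for moving in both comparisons, which have the largest smaller difference, and those named for a single array. The alternatives were another filter or none, every probe set or the mean of a gene's probe sets, no intensity trend, no term for time or for genotype, only the arrays compared, quantile normalization again, centring on ribosomal protein genes, other fold thresholds, and each array left out in turn. The linear-scale alternative did not apply to log2 values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.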

Results

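Transcript levels were measured in heads of *Drosophila melanogaster* flies of 3 genotypes, each with 2 arrays, 1 from flies collected at ZT3 and 1 from flies collected at ZT15. ZT (Zeitgeber time) counts the hours from lights-on in a light-dark cycle, so ZT3 lies in the day and ZT15 in the night. The genotypes are labelled control, over-expression of *cbt* and RNAi of *cbt*. *cbt* (*cabut*) encodes a zinc finger transcription factor known to respond to dietary sugar and to repress the gluconeogenic gene *Pepck1*. The design asks which head transcripts differ when *cbt* is raised or lowered, and how day-night differences compare between the genotypes. The arrays had medians of 7.35 to 7.42 on the log2 scale. Across the 5489 genes tested, Pearson's r was 0.976 to 0.980 between the 2 arrays of 1 genotype and 0.883 to 0.962 between arrays of different genotypes at 1 time. Genes are not independent replicates in these correlations. The labels do not say that the arrays of a genotype came from separate crosses or cultures, so the p-values cover only these 6 arrays. With 1 array per genotype and time, the spread they rest on is the departure from additive effects of both, together with array noise.

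The *cbt* signal went against the labels. The single *cbt* probe set read 10.21 at ZT3 and 10.72 at ZT15 on the control arrays, 8.98 and 9.90 on the over-expression-labelled arrays, and 10.99 and 11.05 on the RNAi-labelled arrays. On the over-expression-labelled arrays it was 2.04-fold lower than on the control arrays, a log2 difference of -1.03 ± 0.20 (SE, 2 arrays against 2) with a 95% interval of -1.52 to -0.54 and an adjusted p of 0.0331. On the RNAi-labelled arrays it lay 0.55 above control, with an interval of 0.06 to 1.04 that did not pass after adjustment (adjusted p = 0.104). Between the 2 altered genotypes it differed by -1.58 (adjusted p = 0.00413). The lower call against control was lost without the control ZT3 array (adjusted p = 0.186), the control ZT15 array (0.233) or the over-expression-labelled ZT3 array (0.0830), with differences of -1.04, -1.01 and -0.71, and without the time term (0.122). The difference on the RNAi-labelled arrays passed without either over-expression-labelled array (0.0282 and 0.0289), with only the 2 genotypes compared (0.0260) and, at 0.88, without the RNAi-labelled ZT15 array (0.0384), and was 0.22 without the RNAi-labelled ZT3 array. Where the probe set lies in the transcript, and which part the transgenes carry, is not given in the sources used here. Genotypes are therefore named by their labels throughout, and no direction below is tied to a known level of *cbt*.

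**Figure D1:**
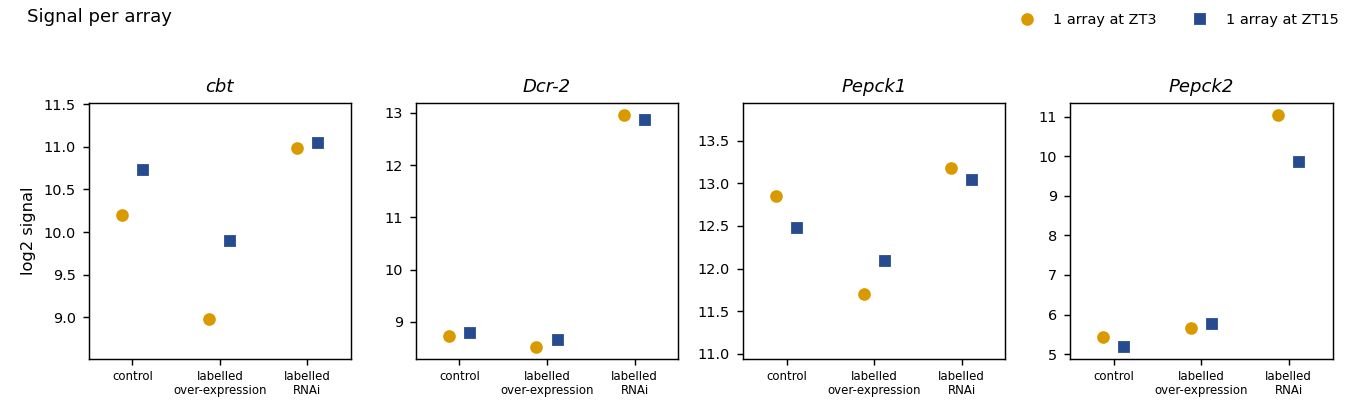
Signal of cbt, Dcr-2, Pepck1 and Pepck2 per array, on the log2 scale (vertical axes, each with its own range), for the 3 genotypes (horizontal axis), with circles for the ZT3 array and squares for the ZT15 array. The cbt points of the over-expression-labelled arrays, at 8.98 and 9.90, lie below both control arrays, and Dcr-2 and Pepck2 stand apart only on the RNAi-labelled arrays.

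Several immune genes were higher in heads of the over-expression-labelled genotype than in control heads. *Def*, which encodes the antimicrobial peptide Defensin, was 25.6-fold higher (log2 4.68 ± 0.46 SE, 2 arrays per genotype, adjusted p = 0.00756). *PGRP-SC2*, an amidase that degrades bacterial peptidoglycan, was 13.9-fold higher (3.80 ± 0.39, adjusted p = 0.00756), at 11.51 on the ZT3 array and 9.81 on the ZT15 array. Of the 10 antimicrobial peptide and recognition genes tested, 7 rose and 0 fell (9 passed when adjusted over the list alone), with a median log2 difference of 1.79. Against the other genes the list shifted upward (camera adjusted p = 1.7e-06), and with an estimated correlation the adjusted p was 0.667. The over-expression-labelled ZT3 array had 56 genes at least 4-fold above every other array and all 13 digestive tract markers on the table at their highest. The camera call held without it, but that fit leaves 1 array of the genotype, so the spread comes from the other genotypes. At ZT15 alone *Def* lay 5.12 and *PGRP-SC2* 3.25 above control. The peptide genes *DptB* and *Drs* differed by 3.58 and 3.51 without passing over all genes (adjusted p = 0.0692 and 0.0836). *TotC*, a Turandot stress gene, rose by 2.12 on the log2 scale and was the only 1 of 7 stress protein genes to pass, with 1 adjusted over the list alone. *Sid*, which encodes a stress-induced DNase, rose 5.91-fold (2.56 ± 0.14, adjusted p = 0.00223). The hemocyte marker list held 3 genes that rose among 12 (6 adjusted over the list alone), including *Hml* at 1.02 and the basement membrane genes *vkg* at 0.68 and *Ppn* at 0.50, but as a list it did not pass (camera adjusted p = 0.0664). It did with the arrays quantile normalized again (0.0228).

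**Figure D2:**
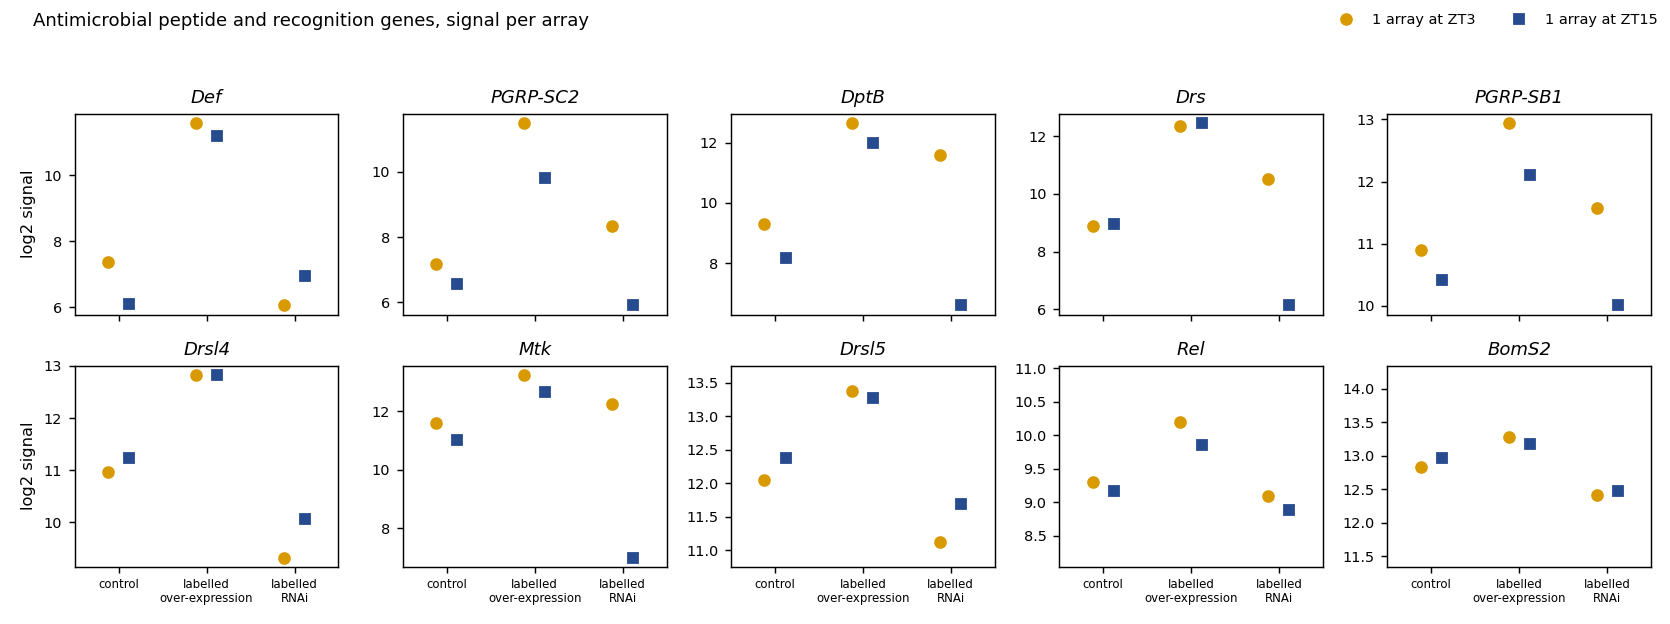
Signal per array of the 10 antimicrobial peptide and recognition genes tested, on the log2 scale (vertical axes, each with its own range), for the 3 genotypes (horizontal axis), with circles for the ZT3 array and squares for the ZT15 array. Def read 11.60 and 11.21 on the over-expression-labelled arrays against 7.36 and 6.09 on the control arrays, while Mtk read 12.24 on the RNAi-labelled ZT3 array and 6.99 on the ZT15 array.

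*tobi*, *whe* and *Act88F* were also among the genes that rose most in the over-expression-labelled genotype, and 10 of 33 detoxification genes rose. *tobi*, a glucosidase gene known as a target of insulin and glucagon-like signals, was 15.2-fold higher (3.92 ± 0.52, adjusted p = 0.0151). *whe* was 26.1-fold higher (4.71 ± 0.68, adjusted p = 0.0184), with 6.16 at ZT3 and 3.25 at ZT15, and *Act88F*, the flight muscle actin gene, 6.78-fold higher (2.76 ± 0.54, adjusted p = 0.0340), with 3.96 and 1.56. Of the detoxification genes 2 fell (17 changed adjusted over the list alone), and among those that rose were the cytochrome P450 genes *Cyp309a2* at 2.18, *Cyp6a23* at 1.51 and *Cyp4p1*, 2.46-fold higher. The list shifted upward (camera adjusted p = 0.0104, and an adjusted p of 0.667 with an estimated correlation), a call lost without the over-expression-labelled ZT3 array (adjusted p = 0.0735). *Act88F* was the only called gene of 16 muscle markers (1 adjusted over the list alone), a list that did not shift (camera adjusted p = 0.700). On that same ZT3 array the 13 digestive tract markers on the table, all below the signal filter and so not tested, were each at their highest. Their median lay 2.99 log2 units above the mean of the other 5 arrays. Of them 7 lay 5-fold or more above every other array, while some were barely highest, such as *Jon66Ci* at 5.08 against 4.99. With no filter they shifted upward as a list (camera adjusted p = 0.00536, and 0.710 with an estimated correlation). On the over-expression-labelled ZT15 array their median excess over the other genotypes was 0.108.

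Some neuronal and hormone-response genes were lower in the over-expression-labelled genotype, and their lists shifted downward by camera but not with an estimated correlation (adjusted p = 0.667 for both). Of 12 neuron markers 4 fell and 0 rose (7 adjusted over the list alone): *VAChT*, the vesicular acetylcholine transporter, at -0.84, the presynaptic calcium channel gene *cac* at -0.65, the complexin gene *cpx* at -0.57 and *Snap25* at -0.51. Of 14 neuropeptide genes 3 fell and 0 rose (4 adjusted over the list alone), namely *Pdf*, the peptide of the ventral clock neurons, at -0.91, *sNPF* at -0.58 and *AstC* at -0.57. In the ecdysone and juvenile hormone list 4 of 9 genes fell and 0 rose (6 adjusted over the list alone), among them the juvenile hormone response gene *Kr-h1* at -1.36, *Hr3* at -0.77 and the ecdysone receptor gene *EcR* at -0.57. In phototransduction 1 of 20 genes fell, the kinase gene *Gprk1* at -0.45 (0 adjusted over the list alone). Camera adjusted p was 0.000562 (neuron), 0.0104 (neuropeptide), 0.00572 (hormone response) and 0.00572 (phototransduction), and with an estimated correlation each list had an adjusted p of 0.667. The phototransduction call was lost without the control ZT3 array (0.106) or the over-expression-labelled ZT3 array (0.264), and so was the neuropeptide call (0.0705 and 0.264), while the neuron and hormone-response calls held in each of the 6 fits with 1 array left out. Each of those 6 fits leaves 1 array in 1 genotype and again takes a correlation of 0.01. The estimated correlation was 0.75 for neuron markers and 0.33 for the hormone-response list. The mean signal of the neuron markers was 9.29 and 9.64 on the over-expression-labelled arrays at ZT3 and ZT15. On the control arrays it was 9.91 and 9.98. The gap between the 3' and 5' control probe sets, in the same order, was 5.98 and 6.13 against 5.71 and 5.53 for eIF4a, and 3.67 and 3.94 against 3.67 and 3.61 for GAPDH. On the over-expression-labelled ZT3 array, where 56 genes stood apart, the middle 18S ribosomal RNA probe set read 7.36 against 8.79 to 10.77 on the others.

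Single metabolic genes fell in the over-expression-labelled genotype, although no metabolic list shifted with all 6 arrays. The perilipin gene *Lsd-1*, which coats lipid droplets, fell by 1.70 on the log2 scale (adjusted p = 0.0178), *hgo*, of tyrosine breakdown, fell by 1.19 (0.0227), *Tat* fell by 0.77 (0.0201) and *Pepck1*, of gluconeogenesis, fell by 0.77 (0.0446). Gluconeogenesis and amino acid breakdown counted 3 lower genes of 10 (3 adjusted over the list alone), glycolysis 2 lower of 10 (6), with *Hex-A* at -0.53 and *Tpi* at -0.44, fatty acid synthesis 2 lower of 12 (2), with *Men* at -0.82 and *bgm* at -0.64, and lipid mobilisation 4 lower of 17 (4), with *Acox57D-d* at -0.92, *yip2* at -0.78 and *Lsd-2* at -0.48. Sugar transport and storage counted 3 higher and 1 lower of 10 (5), with *sut1* at 0.67 and *AGBE* at 0.59. Of the 14 sugar-responsive genes, 1 rose and 4 fell (7), including *Lst*, a hormone gene known to limit insulin release, at 0.88 and the transcription factor gene *foxo* at -0.85. Camera adjusted p for these lists ran from 0.130 to 0.424. Gluconeogenesis passed as a list without the control ZT15 (0.0228) or over-expression-labelled ZT15 array (0.00978), and without the control ZT15 array so did lipid mobilisation (0.0124), the respiratory chain (0.0027) and muscle markers (0.0278). The respiratory chain also passed with the filter at the 60th percentile (0.0297). Fat body markers counted 1 higher and 1 lower of 10 (2 adjusted over the list alone), with the iron carrier gene *Tsf1* at 1.13, glia markers 1 higher and 2 lower of 10 (6), with *Mdr65* at 0.79 and *nrv2* at -0.66, and the male list 1 lower of 4 (1), *sxe2* at -1.72. By limma no cytosolic ribosomal protein gene of 29, respiratory chain gene of 55, photoreceptor marker of 3 or female marker of 5 passed over all genes, with 3, 8, 0 and 1 at an unadjusted p under 0.05. The stress protein list had a median below 0 (-0.08) and a mean above it (0.34), and the glia list a median of 0.02 and a mean of 0.00 with a downward test, neither of them called. Among genes with a symbol the largest decreases were in the odorant-binding protein genes *Obp56h* (5.23-fold, adjusted p = 0.0269) and *Obp19b* (4.49-fold, 0.0355) and in *phu* (4.83-fold, 0.0299).

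Of the 5489 genes, 635 differed between the over-expression-labelled and control genotypes, 346 higher and 289 lower, and 143 of them at least 2-fold, 42 of those lower. At an unadjusted p under 0.05 there were 1844. Without the model, 311 genes lay at least 1.5-fold apart in 1 direction at both times (198 higher, 113 lower) and 2 in opposite directions. With 1 array left out the count of changed genes was 0 without the control ZT3 array by limma (1216 at an unadjusted p under 0.05), 7 without the control ZT15 array and 231 without the over-expression-labelled ZT3 array, so every gene call above was lost in at least 1 of these fits. The 1.5-fold count without either ZT15 array, at ZT3 alone, was 660.

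The largest rises in heads of the RNAi-labelled genotype against control were in 3 transcripts. *Pepck2*, a paralog of the gluconeogenic enzyme gene *Pepck1*, was 35.2-fold higher (log2 5.14 ± 0.29 SE, 2 arrays per genotype, adjusted p = 0.00229), reading 11.04 and 9.85 on the RNAi-labelled arrays against 5.44 and 5.18 on the control arrays. *Cyp4e3*, a cytochrome P450 gene, was 22.8-fold higher (4.51 ± 0.33, adjusted p = 0.00263). *Dcr-2*, which encodes the Dicer that makes small interfering RNAs, was 17.8-fold higher (4.15 ± 0.10, adjusted p = 0.000131), at 12.96 and 12.87 against 8.74 and 8.79. *Pepck1* itself lay 0.44 above control without passing (adjusted p = 0.123). *Cyp6a8* (2.32), *jef* (2.28), the odorant-binding protein gene *Obp28a* (2.17) and the adenylate kinase gene *Adk3* (2.16) also rose, as did the noncoding *lncRNA:CR32553* (2.42). The Turandot gene *TotC* was 31.7-fold lower (-4.98 ± 0.31, adjusted p = 0.00229), the P450 gene *Cyp6a17* 27.5-fold lower (-4.78 ± 1.01, adjusted p = 0.0326; -6.91 at ZT3 and -2.65 at ZT15), *Rcd7* 10.7-fold lower (-3.42, adjusted p = 0.00124) and *Sid* 4.81-fold lower (-2.26, adjusted p = 0.00229).

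Some phototransduction genes were higher and some hemocyte genes lower in the RNAi-labelled genotype, and their lists shifted by camera but not with an estimated correlation (adjusted p = 0.916 for both). Of 20 phototransduction genes 5 rose and 0 fell (12 adjusted over the list alone), among them *rdgA*, a diacylglycerol kinase gene, at 0.83, the light-gated channel gene *trpl* at 0.68 and the visual G protein gene *Gbeta76C* at 0.59. The photoreceptor markers *eys* (adjusted p = 0.0373) and *gl* at 0.47 rose too, 2 of 3 tested (3 adjusted over the list alone). Of 12 hemocyte markers 7 fell and 0 rose (12 adjusted over the list alone), including the prophenoloxidase gene *PPO1* at -1.08, the GATA factor gene *srp* at -0.78 and the phagocytosis receptor gene *NimC1* at -0.65. These were the 2 lists that shifted, with camera adjusted p of 0.0103 for phototransduction and 0.0121 for hemocyte markers. Both calls held in each of the 6 fits with 1 array left out. Each of those fits leaves 1 array in 1 genotype and again takes a correlation of 0.01. The estimated correlation was 0.47 for phototransduction and -0.054 for hemocyte markers. The hemocyte call was lost with the filter at the 60th percentile (0.0557). The phototransduction call was lost with the mean of a gene's probe sets (0.160). The gap between the 3' and 5' control probe sets was 3.83 and 4.24 on the RNAi-labelled arrays at ZT3 and ZT15 against 3.67 and 3.61 on the control arrays for GAPDH, and 5.66 and 5.51 against 5.71 and 5.53 for eIF4a. The control probe set AFFX-BioB-3_at read 7.93 and 7.76 against 4.71 and 5.54. *Galphaq*, a visual G protein gene of the phototransduction list named here after its values were seen, had further probe sets that moved the other way, at -1.24 and -1.64 against 0.27 for the one used. The value of *rdgA* is the largest of its 4 probe sets, the others reading 0.48, 0.14 and 0.10. With their mean it was 0.39 and did not pass (adjusted p = 0.154).

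Metabolic and immune genes moved singly in the RNAi-labelled genotype. *Lst* fell by 1.39 (adjusted p = 0.00321) and *foxo* fell by 0.94 (0.0166) on the log2 scale, within 3 higher and 3 lower of 14 sugar-responsive genes (8 adjusted over the list alone). The glucose transporter gene *Glut1* rose by 0.89 (adjusted p = 0.0388), 1 higher of 10 sugar transport genes (0). Dimmer probe sets of *Glut1* differed by 0.41 and -0.05. The hexokinase gene *Hex-A* rose by 0.47 (0.0466), 1 higher of 10 glycolysis genes (0). Gluconeogenesis counted 1 higher and 1 lower of 10 (2), *Pepck2* and the polyamine gene *Odc1* at -1.05. Fatty acid synthesis counted 2 lower of 12 (2), *mdy* at -0.68 and *Agpat3* at -0.51, and lipid mobilisation 1 higher and 5 lower of 17 (8), with *Lsd-2* at 0.57, *Acox57D-d* at -0.92 and *Arc42* at -0.72. Of the immune list 3 fell and 0 rose of 10 (3), with *Drsl4* at -1.41 and *Drsl5* at -0.81, and of the stress list 2 fell of 7 (2), *TotC* and *stv* at -0.92. Detoxification counted 6 higher and 6 lower of 33 (16), neuropeptides 1 higher and 2 lower of 14 (7), with *SIFa* at 0.69 and *Nplp3* at -0.61, and the hormone-response list 1 higher and 2 lower of 9 (4), with *MsrA* at 0.58, *Hr3* at -0.59 and *Eip93F* at -0.47, whose difference was 0.06 as the mean of its probe sets. Glia markers counted 2 higher and 3 lower of 10 (5), with *pippin* at 0.69, *alrm* at -0.80 and *e* at -0.76, fat body markers 1 lower of 10 (3), *Mtp* at -0.49, muscle markers 1 lower of 16 (1), *Zasp52* at -0.57, and female markers 1 lower of 5 (1), *fit* at -1.69. The ribosomal protein gene *RpS29*, 1 of 29, at -0.25, and the respiratory chain gene *COX7AL2*, 1 of 55, at -0.84, fell (0 in each list alone). By limma no neuron marker of 12 and no male marker of 4 passed (3 and 0 at an unadjusted p under 0.05). Camera adjusted p for these lists ran from 0.154 to 0.842. The immune list passed without the RNAi-labelled ZT3 array (0.000351), detoxification without the RNAi-labelled ZT15 array (0.0229), and lipid mobilisation without that array (0.0229) or the control ZT15 array (0.00534), all downward. Median and mean differed in sign for ribosomal proteins (0.00 and -0.01), neuron markers (just below 0 and 0.03) and the core clock (-0.03 and 0.03).

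In total 934 genes differed between the RNAi-labelled and control genotypes, 343 higher and 591 lower, 149 of them at least 2-fold (44 higher, 105 lower), with 2041 at an unadjusted p under 0.05. Of the calls 36.7% were higher, and 52.7% were higher when each array was centred on the ribosomal protein genes. At least 1.5-fold apart in 1 direction at both times were 358 genes (117 higher, 241 lower), and 6 in opposite directions. The count of changed genes was 15 without the control ZT3 array, 3 without the control ZT15 array, 304 without the RNAi-labelled ZT3 array and 441 without the RNAi-labelled ZT15 array. *Dcr-2* and *jef* were among the genes called in each of these fits. The 1.5-fold count was 685 at ZT15 alone, without either ZT3 array, and 611 at ZT3 alone.

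With all 6 arrays more genes passed between the 2 altered genotypes than between either and control. This order turned without the RNAi-labelled ZT3 array or the over-expression-labelled ZT3 array. Between the altered genotypes those fits compare 2 arrays with 1, but 2 with 2 for the other genotype and control. The counts there are not on equal terms and do not show which difference is larger. *TotC* was 138-fold higher on the over-expression-labelled than on the RNAi-labelled arrays (log2 7.10 ± 0.31 SE, 2 arrays per genotype, adjusted p = 0.000352), *Def* 29.9-fold (4.90 ± 0.46, adjusted p = 0.00179), *Sid* 28.4-fold (4.83 ± 0.14, adjusted p = 0.000163), *tobi* 22.7-fold (adjusted p = 0.0033) and *whe* 21.3-fold (adjusted p = 0.00717). The peptide gene *Drs* was 17.1-fold higher (adjusted p = 0.0326; 1.85 at ZT3 and 6.34 at ZT15). *Cyp4g1*, a P450 gene of hydrocarbon synthesis, was 24.0-fold higher (adjusted p = 0.0286), with 7.12 at ZT3 and 2.05 at ZT15. *Pepck2* was 26.5-fold lower, *Dcr-2* 20.2-fold lower, *Cyp4e3* 13.0-fold lower and *Obp19b* 6.52-fold lower. The antimicrobial list had 8 higher of 10 genes and a median of 3.18, the hemocyte list 9 higher of 12, with *PPO1* and *vkg* at 1.18, the detoxification list 16 higher and 3 lower of 33, and the clock output list 8 higher and 2 lower of 14, with *Cpr72Ec* at 2.64. Phototransduction had 15 lower of 20, with *rdgA* at -1.42 (-0.69 with the mean of its probe sets), neuron markers 8 lower of 12, with *nSyb* at -0.94 and *cac* at -0.86, neuropeptides 10 lower and 2 higher of 14, with *SIFa* at -0.92 and *Pdf* at -0.80, and gluconeogenesis 6 lower and 1 higher of 10, with *hgo* at -1.47 and *Pepck1* at -1.22. Adjusted over the list alone these 8 lists counted 10, 9, 23, 11, 16, 8, 12 and 7 genes.

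In all, 9 lists shifted between the 2 altered genotypes, the 8 above with camera adjusted p from 2.5e-05 for antimicrobial genes to 0.0371 for gluconeogenesis, and the respiratory chain upward (0.0443), where 4 of 55 genes rose and 0 passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.622 for the antimicrobial and hemocyte lists and 0.747 for the other 7. No list call in any comparison passed there. That test takes only the 2 residual degrees of freedom of the fit and also allows for the correlation between genes of a list. Where that correlation is high, the loss may come from either. The estimate was 0.75 for neuron markers, 0.47 for phototransduction and for neuropeptides, 0.40 for gluconeogenesis, 0.25 for detoxification and 0.21 for the respiratory chain. It was 0.050 for antimicrobial, 0.013 for clock output and -0.054 for hemocyte genes. The unadjusted camera p of the hemocyte list between the altered genotypes still went from 9.2e-05 to 0.054. The respiratory chain call was lost with the arrays quantile normalized again (0.281), centred on ribosomal proteins (0.292), or without the over-expression-labelled ZT3 (0.226), over-expression-labelled ZT15 (0.0934) or RNAi-labelled ZT15 array (0.237), and the gluconeogenesis call with ribosomal protein centring (0.0744). With no filter the respiratory chain (0.0818) and neuropeptide calls (0.0563) were lost, with the filter at the 60th percentile the respiratory chain (0.0517), detoxification (0.0517) and gluconeogenesis calls (0.121), and with the mean of a gene's probe sets the respiratory chain call (0.0674). The hormone-response list passed without the over-expression-labelled ZT3 (0.0476) or RNAi-labelled ZT15 array (0.0487), and so did the sugar-responsive list without the latter (0.0487). Median and mean differed in sign for glia (-0.03 and 0.07) and fat body markers (0.01 and -0.07). Among other genes *Lst* (2.27), *fit* (1.75) and *Tsf1* (0.90) were higher and *Glut1* (-1.70), *Lsd-1* (-1.64), *Kr-h1* (-1.23), *daw* (-1.18) and *Hex-A* (-0.99) lower. Dimmer probe sets of *Glut1* differed from control by -0.31 and 0.08 on the over-expression-labelled arrays and by 0.41 and -0.05 on the RNAi-labelled arrays. *Tsf1* had a difference of -0.35 when its probe sets were averaged. In all 1983 genes differed, 1017 higher and 966 lower, 377 at least 2-fold (268 and 109), with 2612 at an unadjusted p under 0.05. Of these calls 51.3% were higher, against 39.1% with ribosomal protein centring, which moved the median of all genes to -0.10. At least 1.5-fold apart in 1 direction at both times were 683 genes (460 higher, 223 lower), with 2 in opposite directions and 1393 at ZT3 alone.

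Set side by side, the changes of the 2 altered genotypes against control had little correlation. Across genes, the log2 differences had a Pearson's r of -0.031, where unchanged groups sharing the control arrays gave 0.495 in 100 simulations. The covariance was -0.0055 against a simulated 0.0082, a difference of -0.014. The control arrays were too few to split into groups of 2, but pairs of differences with no shared array gave r of -0.115 and -0.011. Changed in both comparisons were 189 genes, 90 in the same direction (36 higher, 54 lower) and 99 in opposite directions. Lists of these sizes drawn independently would share 52.7 genes in the same direction and 55.3 in opposite directions. Unchanged groups sharing the controls gave 0.18 in the same direction, a count low by construction, since few genes pass where none is changed. Part of the excess in the same direction may come from the shared control arrays. Both comparisons also come from 1 fit and share the SE of each gene. Genes with a small SE therefore tend to pass in both, in either direction, which independent lists do not allow for. Of the opposite genes 86 were higher in the over-expression-labelled and lower in the RNAi-labelled genotype, against 37.3 for independent lists, led by *Sid*, *TotC* and the peptide gene *Drsl4* (1.72 and -1.41). The reverse held for 13, against 18.1. In the same direction, the P450 genes *Cyp6a23* (1.51 and 1.76) and *Cyp4p1* (2.46-fold and 2.75-fold) and *jef* (1.35 and 2.28) rose in both, and *Cyp6d2* (-1.44 and -1.77) fell in both. Without the control ZT3 or the control ZT15 array both counts were 0 by limma, without the over-expression-labelled ZT3 array they were 56 and 57, without the RNAi-labelled ZT3 array 70 and 57, without the RNAi-labelled ZT15 array 52 and 113, and without the over-expression-labelled ZT15 array 113 and 186.

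**Figure D3:**
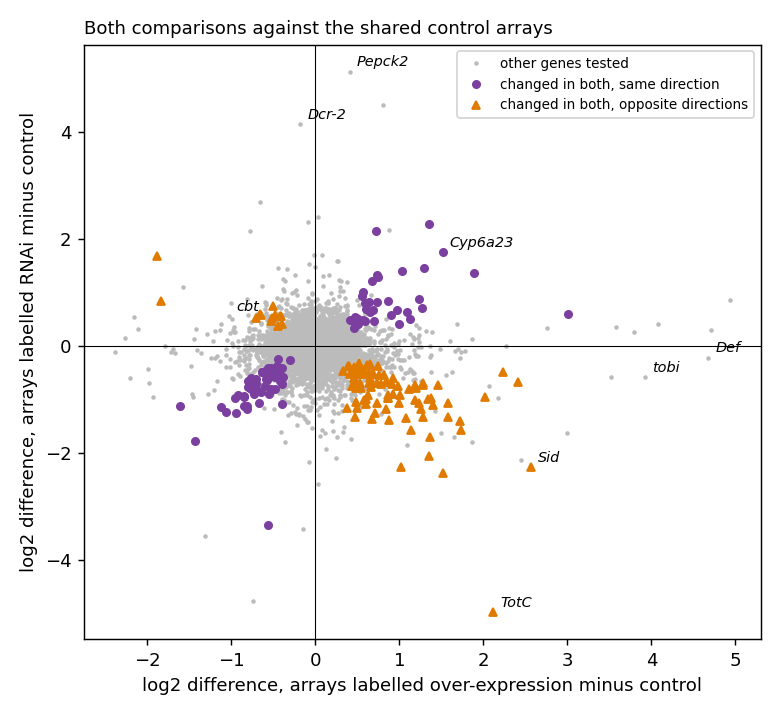
Log2 difference from control of each of the 5489 genes tested, for the over-expression-labelled genotype (horizontal axis) and the RNAi-labelled genotype (vertical axis), 2 arrays per genotype. Circles mark the 90 genes changed in both in the same direction, triangles the 99 changed in opposite directions, and grey points the other genes. The points show no common slope (r = -0.031), and 86 of the triangles lie at the lower right.

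The 3 largest day-night differences among called genes were in core clock genes. Over the 3 genotypes, *vri*, a clock repressor gene, was 8.30-fold higher at ZT15 than at ZT3 (log2 3.05 ± 0.11 SE, 3 arrays per time, adjusted p = 0.00114), *tim* 6.47-fold (2.69 ± 0.22, adjusted p = 0.0107) and *per* 5.60-fold (2.49 ± 0.10, adjusted p = 0.00114). *Pdp1* was higher by 0.72 (adjusted p = 0.0235), and *Clk*, the activator of *per* and *tim*, 3.93-fold lower (-1.98 ± 0.25, adjusted p = 0.0328), with the photoreceptor gene *cry* 2.06-fold lower (-1.05 ± 0.10, adjusted p = 0.0170). Each of these 6 moved in 1 direction in all 3 genotypes. They were 4 higher and 2 lower of 10 core clock genes tested (8 adjusted over the list alone), a list that has members moving both ways and did not shift (camera adjusted p = 0.0856), although it did without either over-expression-labelled array (0.0143 and 0.0181), with no filter (0.0487) and with the filter at the 60th percentile (0.0323). Outside the core, the clock output genes *Usp8* (2.10), *Slob* (1.60, or 1.01 with the mean of its probe sets) and *Ugt35B1* (-1.92) changed, within 3 higher and 4 lower of 14 (11 adjusted over the list alone), and so did *gol* (1.74, or 1.05 with the mean of its probe sets), *Obp99a* (1.52), *Nmdmc* (-1.06), *rost* (-0.93) and *Acsx3* (-0.88).

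With all 6 arrays fewer genes changed with time than between genotypes. Of 5489 genes 83 passed, 41 higher and 42 lower at ZT15, 22 of them at least 2-fold (15 and 7), with 902 at an unadjusted p under 0.05. The count was 6 without the control ZT3 array, where 0 (by limma, 1216 at an unadjusted p under 0.05) and 15 genes differed from control in the over-expression-labelled and RNAi-labelled genotypes, and 7 without the control ZT15 array, where 7 and 3 did. *vri*, *per*, *Usp8*, *gol* and *Ugt35B1* were called in both of these fits, while *tim*, *Clk*, *cry* and *Pdp1* had adjusted p from 0.155 to 0.297. Detoxification genes were lower at night, 4 of 33 (11 adjusted over the list alone), among them *Ugt302C1* at -0.69 and *Cyp4p1* at -0.67 (camera adjusted p = 0.00418, and an adjusted p of 0.700 with an estimated correlation), a call lost without the control ZT3 (0.0597) or ZT15 array (0.0590). The respiratory chain list shifted upward at night by a median of 0.09 (camera adjusted p = 1.6e-06, and an adjusted p of 0.700 with an estimated correlation), although by limma no single gene of 55 passed (5 at an unadjusted p under 0.05, 0 adjusted over the list alone). Single genes of other lists passed: the hormone-response gene *MsrA* at 0.93 (1 of 9, and 1 adjusted over the list alone), *mdy*, of triglyceride synthesis, at -0.82 (1 of 12, and 4), the eye factor gene *gl* at 0.68 (1 of 3, and 3) and *inaC*, the eye protein kinase C gene, at -0.52 (1 of 20, and 2). By limma no gene passed in the other 16 lists tested, which had 0 to 4 genes each at an unadjusted p under 0.05 and 0 to 3 adjusted over the list alone. Median and mean of the neuropeptide list differed in sign (-0.01 and 0.01). Several uncalled lists passed with 1 array left out: without either over-expression-labelled array gluconeogenesis downward (0.00027 and 0.000267), fatty acid synthesis and phototransduction downward and muscle markers upward, and without either RNAi-labelled array immune genes (0.0163 and 0.0134), hemocyte markers and lipid mobilisation downward and neuron markers, muscle markers and hormone-response genes upward. With no filter immune genes (0.0205), hemocyte markers (0.0465) and digestive tract markers (0.00408) passed downward. The 13 digestive tract markers were each highest on the over-expression-labelled ZT3 array, so 1 array weighs on their call. With the filter at the 60th percentile hemocyte markers passed downward (0.0475) and hormone-response genes (0.0475) and muscle markers (0.0484) upward. Hemocyte markers also passed downward with the arrays quantile normalized again (0.0353).

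Day-night differences of the core clock genes were also read within each genotype. In the control, over-expression-labelled and RNAi-labelled genotypes, in that order, *per* differed by 2.41, 2.67 and 2.38, *tim* by 2.44, 2.24 and 3.40, *vri* by 2.94, 2.88 and 3.34, *Clk* by -2.30, -2.46 and -1.16, and *cry* by -1.19, -1.16 and -0.79. *Pdp1* differed by 0.87, 0.59 and 0.72, *cwo* by 0.57, 1.03 and 0.29, *dco* by -0.64, -0.07 and -0.32, *cyc* by -0.18, -0.18 and -0.08, and *slmb* by 0.10, -0.13 and 0.11. The median absolute difference of the 10 clock genes tested was 1.03, 1.09 and 0.754. These come from 1 pair of arrays per genotype, so no difference between genotypes in the day-night change was tested. Averaged over both times, *per* was higher than control in both altered genotypes (0.57, adjusted p = 0.0416, and 0.48, adjusted p = 0.0499), *cwo* was lower in the over-expression-labelled genotype (-0.85, adjusted p = 0.0389), and *cyc* (0.39, adjusted p = 0.0364) and *cry* (0.59, adjusted p = 0.0320) were higher in the RNAi-labelled genotype. These were 2 of 10 clock genes in the first comparison and 3 of 10 in the second (2 and 3 adjusted over the list alone, camera adjusted p = 0.907 and 0.581), and each of these calls was lost without either control array (adjusted p from 0.110 to 0.315). Clock output genes counted 5 higher of 14 in the over-expression-labelled genotype (6 adjusted over the list alone, camera adjusted p = 0.0646, and 0.0328 and 0.0192 without the control ZT3 and the over-expression-labelled ZT3 array, 0.0383 with the filter at the 60th percentile and 0.0386 with the arrays quantile normalized again), with *Cpr72Ec* at 1.43, and 1 higher and 3 lower in the RNAi-labelled genotype (8, camera adjusted p = 0.274).

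**Figure D4:**
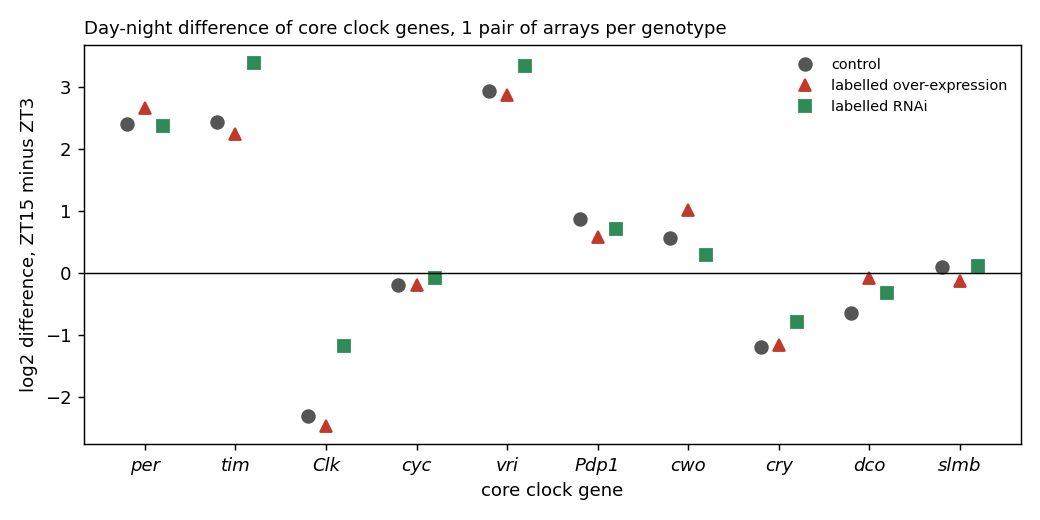
Log2 difference between ZT15 and ZT3 (vertical axis) of the 10 core clock genes tested (horizontal axis), 1 pair of arrays per genotype, with circles for control, triangles for the over-expression-labelled and squares for the RNAi-labelled genotype. In all 3 genotypes per, tim and vri lie above 2 and Clk and cry below 0.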

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

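The tests of the *cbt* signal and of the digestive tract genes were chosen after those results were seen, and the comparison of same-direction genes with chromosome 2 and with tissue markers, and the splits by time, were set before.

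The *cbt* signal was lower on the over-expression-labelled arrays and higher on the RNAi-labelled arrays than on the control arrays. An exchange of these 2 labels may account for it, and the difference of 0.55 on the RNAi-labelled arrays has the direction it needs but did not pass (adjusted p = 0.104). *Dcr-2*, 17.8-fold higher on the RNAi-labelled arrays alone, bears on the labels, since Dicer-2 is often co-expressed with RNAi transgenes, but the labels state no such transgene, and *Pepck1*, known to be repressed by *cbt*, was lower on the over-expression-labelled than on the RNAi-labelled arrays (-1.22, adjusted p = 0.00565), as unexchanged labels would give if that repression acts in these heads. A probe set that reads a part of the transcript which the transgenes lack or carry could also account for it, and with 1 *cbt* probe set this stays open. *Dcr-2*, if it came with an RNAi transgene, and *Pepck1* both run the way unexchanged labels would give. The exchange stays open all the same, since no Dicer-2 transgene is stated and 1 repressed gene does not exclude it. The biological alternative, feedback on the endogenous gene, was not tested.

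Digestive tract genes, which lay below the signal filter, were high on the over-expression-labelled ZT3 array, where their median lay 2.88 above the control ZT3 array. All 13 markers on the table, several of which the head may also express, were highest there, 7 of them by 5-fold or more. These counts restate the pattern, so digestive tract tissue in that sample may be its source but was not put to a test. The protease genes *Jon65Aiv* and *alphaTry*, picked after their values were seen, lay 36.6-fold and 30.2-fold above the next highest array. An effect of the genotype that does not depend on time is argued against by the other array of that genotype, where the median excess was 0.108 (interquartile range 0.498) against a bound of 1.47. Among 56 genes at least 4-fold above every other array there, *osk* (9.38), of the germline, also stood out. So did the mitotic cyclin gene *CycB* (9.22) and *fln* (8.75), of flight muscle. More than 1 tissue may have been carried along, but these genes were picked after they were seen. The female list members *Cp36*, *Cp38*, *Vm26Aa* and *Vm34Ca* were not higher on that array than on the control ZT3 array. They read 4.05 to 5.23 on all 6 arrays, below the signal filter, so they do not settle which tissue it was. The muscle marker mean was 10.18 on the over-expression-labelled ZT3 array and 9.75 to 10.14 on the others. An effect of the genotype at ZT3 alone stays open, since each genotype has 1 array at that time.

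In both altered genotypes 90 genes changed in the same direction against control. A different mix of tissues in both stays open: no marker list moved the same way in both by more than 0.0568 (male markers), under a bound of 0.323, but the outcome set as evidence against, every list under that bound in both, was not met (digestive tract markers 1.67, male markers -0.68 and neuron markers -0.47 in the over-expression-labelled genotype, photoreceptor markers 0.47 and hemocyte markers -0.44 in the RNAi-labelled one), and only fat body and female markers lay under it in both by more than their members' interquartile range (0.0539 to 0.171). The design text calls the controls cyo, and if that means the CyO balancer of chromosome 2, the genes may lie on that chromosome in excess: 44.4% did (40 of 90, exact 95% interval 34.0% to 55.3%) against 39.4% of all genes tested. That interval includes the share of all genes, which had been set as evidence against, but it is wide enough to include an excess too, so it excludes nothing. Unchanged groups sharing the control arrays gave 0.18 such genes in simulations. Few genes pass where none is changed and noise is independent between genes, so that count excludes nothing. Independent lists of these sizes would share 52.7. The shared control arrays, and the SE that each gene shares in both comparisons, may account for part of the 90. A shared effect of both genotypes stays open.

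The 83 genes that changed with time were more than any other split of the 6 arrays into 3 and 3 gave, where the highest was 3. Only 1 of the 10 splits, the real one, reached that count, and 10 splits are too few for a share under 0.05.

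Some genes lay at least 1.5-fold from the reference in opposite directions at the 2 times, a difference that was not tested. There were 2 between the over-expression-labelled and control genotypes (*Nrx-1* and *Scp1*), 6 between the RNAi-labelled and control genotypes (*Def*, *DptB*, *Drs*, *Mtk*, *PGRP-SC2* and a gene without a symbol) and 2 between the altered genotypes (*para* and *sug*). *Mtk* differed from control on the RNAi-labelled arrays by 0.65 at ZT3 and -4.04 at ZT15, and *Drs* by 1.64 and -2.81. *sxe2* differed between ZT15 and ZT3 by -0.82 in the control, 0.87 in the over-expression-labelled and 0.32 in the RNAi-labelled genotype, also without a test.

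Among the control probe sets of the array, AFFX-BioB-3_at was higher on both RNAi-labelled arrays than on either control array, by at least 2.22 on the log2 scale. AFFX-Dm-K01486-1_at was higher than on either control array by at least 2.00 on the over-expression-labelled arrays and 1.43 on the RNAi-labelled arrays. Its target is not named in the sources used here. If it is the yeast GAL4 sequence, a reading of the accession number alone, both altered genotypes carried a driver that the controls lack, which bears on the 90 genes changed in the same direction and was not tested. In the other direction, AFFX-Dm-M15077-1_at read 2.64 and 2.69 on the RNAi-labelled arrays against 5.55 and 7.05 on the control arrays.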

How the results depend on the processing

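The settings for the counts of genes changed in both comparisons were chosen after the data were seen, and the others before. Of the values of named genes under other settings 3207 kept their direction and side of the threshold, 719 lost and 28 gained a call, and 26 reversed. The groups share the numbers of the 2 times, and the time term is that replicate block: without it 169 genes changed in the over-expression-labelled and 413 in the RNAi-labelled genotype, in place of 635 and 934. Without the genotype term 4 genes changed with time, in place of 83. The cause was not tested for these or the values below, except that fewer arrays leave fewer degrees of freedom. The pseudocount alternative was not run, since the values are log2.

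With each array left out in turn, the counts of changed genes were 0 to 873 (over-expression-labelled against control), 3 to 1305 (RNAi-labelled against control), 775 to 1777 (over-expression-labelled against RNAi-labelled) and 6 to 108 (time), and 0 to 113 in the same direction and 0 to 186 in opposite directions in both. Lists shifted numbered 4 to 10, 2 to 4, 8 to 10 and 1 to 8, and the 1.5-fold counts, then from the pair left, were 311 to 660, 358 to 685 and 683 to 1393. The correlation of both comparisons was -0.121 to 0.0882.

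In the same order of comparisons, lists shifted numbered 0, 0, 0 and 0 with an estimated correlation, in place of 6, 2, 9 and 2 with camera. The test with an estimated correlation takes only the 2 residual degrees of freedom, so few lists could pass it. With fry, which tests a list against no change and not against the other genes, 0, 0, 3 and 0 passed. For the RNAi-labelled genotype 1 list shifted with the filter at the 60th percentile and 1 with the mean of a gene's probe sets, and for time 6 shifted with no filter and 6 at the 60th percentile. At 2-fold 103, 108 and 255 genes lay apart at both times, at 1.3-fold 736, 826 and 1305, and with no filter 559, 543 and 1066, with 221 for the RNAi-labelled genotype at the 60th percentile; a lower fold or filter admits more genes by construction. The median clock difference of the control was 0.869 with no filter and at the 60th percentile.

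Signs turned for *Eip93F* (0.059, RNAi-labelled against control) and *Tsf1* (-0.35, between the altered genotypes) with the mean of probe sets, and for *vri* (-0.019, between the altered genotypes) with ribosomal protein centring. With arrays left out, clock genes that had not passed turned sign. Over-expression-labelled against control these were *Clk* (-0.47 to 0.26), *vri* (-0.19 to 0.075), *dco* (-0.13 to 0.32) and *tim* (-0.076 to 0.60). RNAi-labelled against control they were *Pdp1* (-0.042 to 0.18), *dco* (-0.091 to 0.36), *tim* (-0.91 to 0.14), *Clk* (-1.0 to 0.22) and *vri* (-0.34 to 0.10). Between the altered genotypes they were *Clk* (-0.33 to 0.89), *vri* (-0.16 to 0.28), *dco* (-0.24 to 0.17), *per* (-0.050 to 0.23) and *slmb* (-0.21 to 0.024), and for time *slmb* (-0.012 to 0.11). Dim probe sets were not analysed here, which limits what can be said of genes near background.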

Other observations

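The values here were picked after they were seen, and no test was run on them.

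Apart from the digestive tract, the over-expression-labelled ZT3 array held some genes known from the oocyte and early embryo. The thioredoxin gene *dhd* read 10.63 there, the ribosomal protein paralog gene *RpS5b* 9.89, the translational repressor gene *BicC* 8.18, the mitotic cyclin gene *CycB3* 7.69 and the posterior determinant gene *nanos* 7.22. The hydrocarbon synthesis gene *Cyp4g1* reached 12.17 on that array, 25.4-fold above the next highest. The other 5 arrays had 0 to 2 genes at least 4-fold above every other array. The female list members *Cp36*, *Cp38*, *Vm26Aa* and *Vm34Ca* were not higher on the over-expression-labelled ZT3 array than on the control ZT3 array. They read 4.05 to 5.23 on all 6 arrays, below the signal filter.

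The arrays also differed in added and ribosomal RNA. The poly-A spike probe sets had a median of 8.58 on the control ZT15 array and of 5.53 to 6.82 on the others. The 3 probe sets of 18S ribosomal RNA were lowest on the over-expression-labelled ZT3 array: the middle one read 7.36 there and 8.79 to 10.77 on the others, the 3' one 9.28 and 10.52 to 11.95, and the 5' one 6.32 and 7.89 to 10.23.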
